A study of Arabidopsis thaliana with 18 samples.

How the data were processed

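The series profiled messenger RNA from roots of Arabidopsis thaliana seedlings, the thale cress. Per the labels, surface-sterilised seeds were stratified in the cold and grown under long days, and each sample pooled 50 to 100 seedlings. Seedlings 5 days old received 1 µM abscisic acid (ABA, the hormone of drought and osmotic stress) or a mock treatment for 8 h, and the design text speaks of roots of 1 cm. The genotypes were the wild type Col-0, a triple mutant of VND1, VND2 and VND3 (vnd123 below) and a mutant of VND7 (vnd7 below). There were 18 libraries in 6 groups of 3. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. No label gives a batch or a date.

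Per the labels' protocols, RNA was extracted with a plant column kit and libraries were made with a kit that does not mark strand, for paired reads of 150 bases. Per the submitters' processing notes, HISAT2 and HTSeq were used. The genome build, the annotation, the tool versions and the counting options are not given in the sources used here. The deposited table holds whole-number counts of reads per gene as the authors made them, with no normalization. It has 34218 features. Of these, 1385 carry identifiers of non-coding RNA in place of a locus code. Only 42 of them had any reads, and they took at most 0.00106% of the counts of a library. Locus codes were matched to the TAIR10.1 annotation for names and for which genes neighbour or overlap each other, and for nothing else, because the authors' build is not named. Of 32833 locus codes, 32548 were found there and 10804 had a symbol. All columns matched a sample, so 0 columns were left out.

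Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr by group, which left 20869 genes, and library sizes were scaled with TMM factors. One quasi-likelihood model with a coefficient per group was fitted to all 18 libraries, so that every comparison shared 1 estimate of the spread. The common biological coefficient of variation was 0.106. Each comparison was a contrast of this model with a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 fold changes ± SE from that fit. Levels are CPM, the counts scaled to a fixed library total, on TMM-scaled library sizes, as mean ± SD with n = 3. Where a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 reads in a group, the ratio has an exact 95% counting interval. Bounds and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

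Total counts ran from 38325491 to 58705802 per library. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 8.88 to 30.7, so no library was a copy of another. On simulated counts with known changes, the ABA response of vnd123 recovered 76.1% of 1.5-fold, 91% of 2-fold and 100% of 4-fold changes. The comparison of vnd123 with Col-0 in ABA recovered 76.1%, 88.1% and 100%. The interaction of vnd123 with Col-0 recovered 32.8%, 71.6% and 100%. Of 20684 genes fitted in the simulation, 9, 4 and 3 unchanged genes passed in these comparisons. The changes were planted in 67, 67 and 66 genes for the folds of 1.5, 2 and 4. Genes with few reads were not among them, and the simulated genes varied independently.

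Gene lists and the rule for named genes were fixed before the data were examined, as were the comparisons not called added and the alternatives not called added. There were 27 lists with 383 members. BUD2 was dropped because the reference gives its symbol to another locus, and 358 of the remaining 382 members were tested. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation. Counts of members are given over all genes tested and, beside them, adjusted over the list alone. The lists covered ABA receptors, clade A PP2C phosphatases, ABA-response kinases and transcription factors, ABA metabolism and transport, LEA and dehydration genes, NAC regulators, secondary wall transcription factors, cellulose and xylan, lignin, vessel cell death, xylem patterning, procambium, phloem, endodermis, suberin, root hair, root cap, cell cycle, photosynthesis, auxin, cytokinin, jasmonate, defence, hypoxia, iron deficiency, aquaporins and the circadian clock. Photosynthesis genes mark shoot or greening tissue in a root sample.

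The rule named VND1, VND2, VND3 and VND7 in every group. It named the 10 largest changes each way of an ABA response and the 5 largest of a genotype comparison, among genes past the threshold with a mean log2 CPM above 1 and no overlap between the replicates of both groups. It also named up to 4 members of each list past the threshold, smallest p first, or the member with the smallest p where none passed. The text prints all the largest changes of the Col-0 response and of the genotype comparisons, those of the mutants' responses that differ in part, and the first 2 to 4 members of a list. Of the members with the smallest p where none passed, it prints those of the lists it discusses.

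Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, no composition factors, no filter and a stricter filter on low counts, a replicate block, a fit of only the groups compared, a 2-fold minimum, an estimated correlation for the lists, and leaving out each library in turn. Added after seeing the data were the direct comparison of both mutants, the mean of the mock and ABA differences, and a permutation of list means for the interactions. Because the kit does not mark strand, reads of a gene and of an antisense partner cannot be told apart. Of 70 genes examined, those named as largest changes or shared calls and the VND loci, 10 overlap another gene in the reference, VND2, LAC11, LEA7, BCAT-2 and AT3G15450 among them. Values of close paralogs, such as MAF4 and MAF5 or the RBCS and LHCB1 genes, are uncertain where the counting could split their reads. Figures were drawn with matplotlib 3.10.9.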

Results

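The data are gene counts from roots of Arabidopsis seedlings treated for 8 h with 1 µM ABA or mock. Col-0, the triple mutant vnd123 and the mutant vnd7 were each sampled in 3 libraries per treatment, 18 in all. VND proteins are NAC transcription factors that switch on the formation of xylem vessels, the water-conducting cells. Total counts per library were 45201382 to 52030490 in Col-0 mock and 38325491 to 46853414 in Col-0 ABA. In vnd123 they were 50793600 to 52817387 in mock and 39695163 to 55131602 in ABA, and in vnd7 49195956 to 58705802 and 47945973 to 57756275. The first principal component held 62.6% of the variance and separated the 9 ABA libraries from the 9 mock libraries, and the second held 5.12%. The most abundant gene, the beta-glucosidase gene PYK10, took 0.502% to 1.03% of a library's counts. The series title names the question of which ABA changes depend on VND factors.

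The mutated loci had fewer reads in the lines named for them, but were not empty. VND1 was at 1.35 ± 0.12 CPM in Col-0 mock and 0.0492 ± 0.0699 in vnd123 mock (SD, n = 3), where its libraries held 0 to 7 reads. VND2 was at 1.82 ± 0.346 CPM in Col-0 mock and 0.456 ± 0.0115 in vnd123 mock. VND3 was at 3.76 ± 0.168 and 1.51 ± 0.232 CPM in the same groups. VND7 was at 2.32 ± 0.211 CPM in Col-0 mock and 0.396 ± 0.192 in vnd7 mock. In mock, the log2 changes of vnd123 against Col-0 were -4.69 ± 0.72 for VND1 (adjusted p = 0.00134), -2.00 ± 0.24 for VND2 (adjusted p = 0.000121) and -1.32 ± 0.14 for VND3 (adjusted p = 3.15e-05). In vnd7, VND7 changed by -2.56 ± 0.29 in mock (adjusted p = 9.02e-05) and by -4.24 ± 0.30 in ABA (adjusted p = 1.16e-07). In ABA, the vnd123 values were -2.83 ± 0.66 for VND1 (adjusted p = 0.0421), -2.32 ± 0.23 for VND2 (adjusted p = 6.1e-06) and -2.03 ± 0.15 for VND3 (adjusted p = 1.04e-07). The VND1 call in ABA ended without any 1 of 12 libraries. The adjusted p was 0.112 and 0.129 without Col-0 ABA 1 and 3, 0.0512, 0.0601 and 0.0548 without Col-0 mock 1, 2 and 3, 0.192 and 0.15 without vnd123 ABA 1 and 3, 0.0571, 0.0556 and 0.0554 without vnd7 ABA 1, 2 and 3, and 0.0572 and 0.0583 without vnd7 mock 2 and 3.

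Part of the VND family itself rose with ABA. In Col-0, VND7 rose from 2.32 ± 0.211 to 5.58 ± 0.182 CPM, VND2 from 1.82 ± 0.346 to 3.42 ± 0.727 and VND3 from 3.76 ± 0.168 to 5.74 ± 0.364 (SD, n = 3). The log2 changes were 1.27 ± 0.24 (adjusted p = 0.00034), 0.91 ± 0.21 (adjusted p = 0.00209) and 0.61 ± 0.13 (adjusted p = 0.00141). VND1 did not pass, at -0.49 ± 0.50 (adjusted p = 0.506). In vnd7, VND2 rose by 1.37 ± 0.21 (adjusted p = 2.86e-05) and VND3 by 0.52 ± 0.13 (adjusted p = 0.00378). In vnd123, VND7 was at 1.90 ± 0.351 CPM in mock and 2.97 ± 0.762 in ABA, a log2 change of 0.64 ± 0.24 (adjusted p = 0.0532). Its adjusted p was 0.0361 with DESeq2 and 0.0345 with the replicate block, and ranged from 0.0287 to 0.294 when 1 library was left out. In ABA, VND7 was lower in vnd123 than in Col-0 by a log2 change of -0.91 ± 0.24, which did not pass (adjusted p = 0.0786). That adjusted p was 0.0091 with DESeq2, 0.0297 with the replicate block, 0.0333 without vnd7 mock 1 and 0.324 without vnd123 ABA 2. The difference in the VND7 response between vnd123 and Col-0, -0.63 ± 0.34, did not pass (adjusted p = 1).

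**Figure D1:**
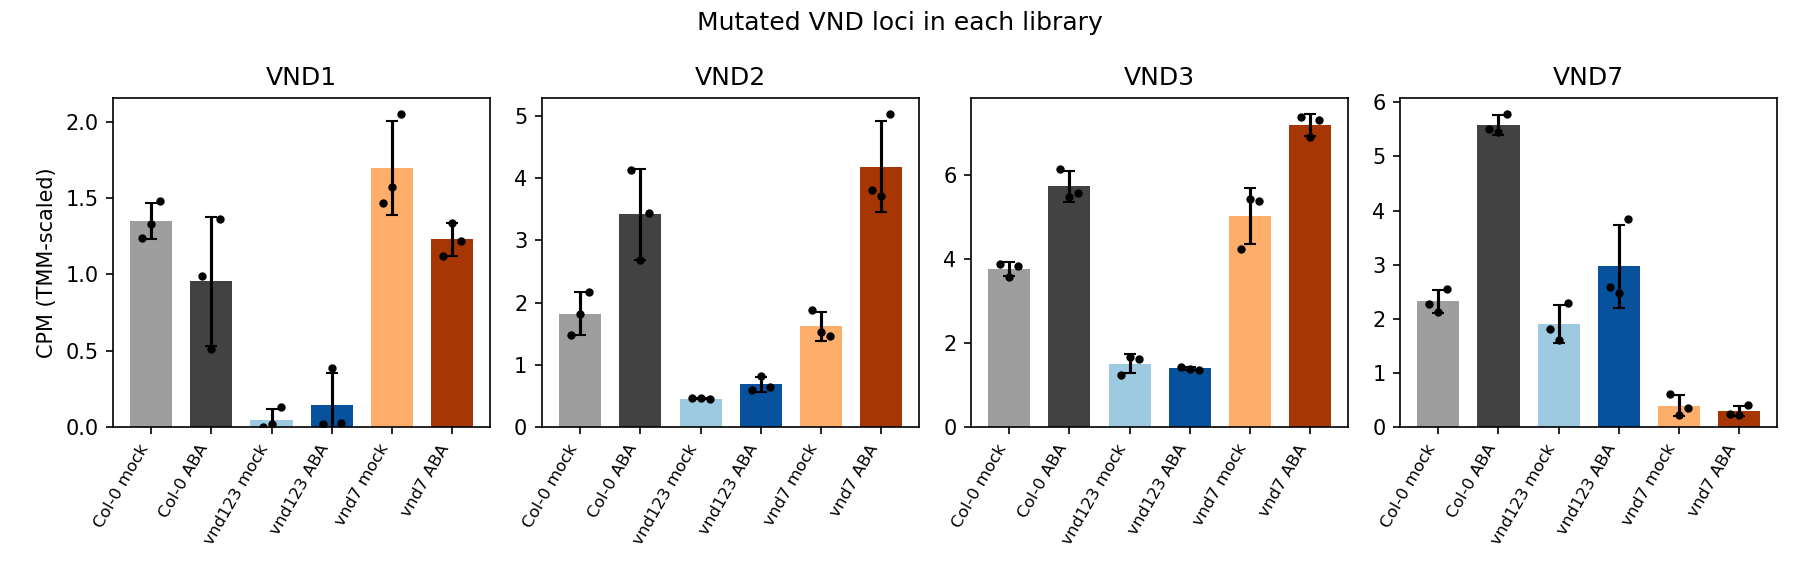
Levels of VND1, VND2, VND3 and VND7 in CPM on TMM-scaled library sizes, with bars for the mean of 3 libraries, error bars for the SD and points for the libraries. VND7 is at 2.32 CPM in Col-0 mock and 5.58 in Col-0 ABA, and at 0.396 and 0.295 in vnd7.

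ABA changed 6532 of 20869 genes in Col-0, and dehydration and ABA-signalling genes were among the largest changes. Of these genes, 3743 were higher and 2789 lower, of which 1213 and 695 changed at least 2-fold. With unscaled library sizes 3050 were higher and 4075 lower. The LEA gene LEA7, which encodes a protective protein of drying tissue, rose from 0.0773 ± 0.0751 to 608 ± 97.6 CPM (SD, n = 3), a log2 change of 12.83 ± 0.29. The beta-glucosidase gene BGLU24 rose by 10.19 ± 0.31 and the dehydration gene RD29B by 10.01 ± 0.42. RD20 (AT2G33380) was at least 409-fold higher, AT5G50360 at least 392-fold and MYB121 (AT3G30210) at least 229-fold. With 1 to 3 reads in mock, the ratio was 4910 for AT3G17520 (95% interval 880 to 194000), 1360 for AT3G27250 (465 to 6590), 1160 for AT4G33467 (208 to 45900) and 635 for the galactinol synthase gene GolS4 (114 to 25100). Among the 10 largest falls, the ABA receptor gene PYL6 went from 70.2 ± 2.11 to 2.2 ± 0.534 CPM, a log2 change of -5.01 ± 0.16. GLIP2, a lipase gene, fell by 5.92 on the log2 scale and AT3G27950 by 6.06. The ratio of AT5G41300 was 0.00175 (4.42e-05 to 0.00977). The glutathione transferase gene GSTF14 fell from 11.6 ± 2.13 to 0.362 ± 0.0392 CPM. The log2 changes of AT3G46400, AT5G40590, AT5G38940, GSL09 and AT1G05700 were -4.87, -4.77, -4.58, -4.46 and -4.44. The largest adjusted p of these 20 genes was 1.16e-07.

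ABA receptor genes mostly fell and genes of the phosphatases that act below them rose in Col-0. Of 11 tested ABA receptor genes, 6 fell and 1 rose (7 and 3 adjusted over the list alone), with a median log2 change of -0.61. PYL6 fell most, PYL4 fell by 2.94, PYL5 by 2.41 and PYR1 by 1.23 on the log2 scale. All 9 clade A PP2C phosphatase genes, whose products the receptors inhibit, rose (9 adjusted over the list alone), with a median of 2.53. HAI1 rose by 5.74 ± 0.29, ABI2 by 3.09 ± 0.16, AHG3 by 2.54 ± 0.16 and ABI1 by 2.00 ± 0.09. Of 17 kinases and transcription factors of the response, 13 rose (14 rose and 1 fell adjusted over the list alone), with HB12 at 6.60 ± 0.50, HB7 at 3.72 ± 0.17, AFP1 at 3.62 ± 0.16 and AFP3 at 1.89 ± 0.11. Of 14 genes of ABA synthesis, breakdown and transport, 7 rose and 1 fell (7 and 1 adjusted over the list alone). CYP707A1, which encodes an enzyme that breaks ABA down, rose from 30 ± 4.85 to 438 ± 62.8 CPM. CYP707A3 rose by 2.75, NCED3, which encodes an enzyme of ABA synthesis, by 3.06, and the ABA exporter gene ABCG25 by 1.09 on the log2 scale. All 20 tested LEA and dehydration genes rose (20 adjusted over the list alone), with LEA4-5 at 8.73, KIN2 at 3.77 and the proline synthesis gene P5CS1 at 2.37. The median of the LEA list was 4.96 as fitted and 4.01 with genes at the floor set to their bound. The lists passed camera with the preset correlation and with an estimated one, where the adjusted p was 0.0194 for the receptors, 0.00762 for the phosphatases, 0.026 for the kinases and transcription factors, 0.0236 for ABA metabolism and 0.000813 for the LEA genes.

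Secondary wall genes rose with ABA in Col-0. The secondary wall is the thickened, lignified layer of vessels. Of 19 cellulose and xylan genes, 17 rose and 0 fell (17 adjusted over the list alone), with a median log2 change of 0.60 (adjusted p = 0.0304 with an estimated correlation). The cellulose synthase gene CESA8 rose from 32.4 ± 1.75 to 58.8 ± 4.96 CPM, a log2 change of 0.86 ± 0.10. The xylan genes GUX1, IRX14-L and GUX2 rose by 1.29 ± 0.10, 1.79 ± 0.15 and 0.71 ± 0.08. Of 17 transcription factors below the NACs, 12 rose (14 adjusted over the list alone), with a median of 0.88 (adjusted p = 0.024 with an estimated correlation). MYB52 rose by 1.56 ± 0.14, MYB20 by 1.70 ± 0.18, MYB43 by 0.79 ± 0.09 and MYB46, a direct target of the VND proteins, by 0.88 ± 0.14. Of 10 NAC regulators, 6 rose (6 adjusted over the list alone), with VND4 at 0.51 and VNI2, an inhibitor of VND7, at 0.59, while the list NAC vascular and fibre wall regulators as a whole did not pass (adjusted p = 0.138, and 0.0287 with no filter on low counts). Of 16 genes of vessel cell death and wall patterning, 8 rose and 1 fell (8 and 1 adjusted over the list alone). The nuclease gene BFN1 rose from 8.9 ± 1.24 to 56.2 ± 4.34 CPM, the peptidase gene XCP1 by 0.79, ROP11 by 0.58 and MIDD1 by 0.66 on the log2 scale. That list passed with the preset correlation (adjusted p = 0.0101) and not otherwise (adjusted p = 0.172 with an estimated correlation). Of 23 lignin genes, 7 rose and 3 fell (9 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.348). PRX71 fell by 3.64, and the dehydrogenase gene CAD5, the laccase gene LAC17 and PRX66 rose by 0.98, 1.33 and 1.37 on the log2 scale.

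Suberin genes, water channel genes and hypoxia genes also rose in Col-0. Of 18 genes of suberin, the waxy barrier of the endodermis, 17 rose (17 adjusted over the list alone), with a median log2 change of 0.96 (adjusted p = 0.0236 with an estimated correlation). The transporter gene ABCG6 rose from 112 ± 8.26 to 364 ± 43.2 CPM, GPAT5 by 1.51, FAR5 by 1.47 and ASFT by 1.14 on the log2 scale. Of 18 aquaporin genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone), led by TIP2;3 at 2.17 ± 0.16 and TIP2;2 at 1.31 ± 0.10 (adjusted p = 0.243 with an estimated correlation). Of 9 hypoxia genes, 7 rose (8 adjusted over the list alone), with the sucrose synthase gene SUS1 at 1.61 ± 0.11 and the alcohol dehydrogenase gene ADH1 at 3.03 ± 0.29 (adjusted p = 0.195 with an estimated correlation). Of 12 genes of the list root hair and epidermis, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with PRP3 at 1.16 and EXPA18 at 0.77 (adjusted p = 0.356 with an estimated correlation). Its preset adjusted p of 0.0415 became 0.0628 without Col-0 ABA 1, 0.056 without Col-0 mock 2 and 0.0511 without vnd7 mock 2. Of 16 genes of the list iron deficiency response, 6 fell and 4 rose (6 and 4 adjusted over the list alone). F6'H1, which encodes an enzyme for coumarins that mobilise iron, fell by 2.51 and the regulator FIT by 1.68 on the log2 scale. That list's adjusted p was 0.016, 0.128 without Col-0 ABA 2, and adjusted p = 0.507 with an estimated correlation.

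The remaining 12 lists did not pass in Col-0 at either correlation, although single members did. Their counts adjusted over the list alone were the same as those over all genes. Of 11 xylem patterning genes 1 rose and 1 fell, TMO5 at 0.46 and SACL3 at -0.37. Of 13 procambium genes 2 rose and 4 fell, with the transcription factor gene LBD4 at -1.89 and WOX14 at -0.90. Of 16 phloem genes 3 rose and 1 fell, with SULTR1;3 at 2.42 and CVP2 at -0.85. Of 11 endodermis genes CASP5 rose by 1.99 and SCR was at -0.21, a call that ended without Col-0 ABA 3 (adjusted p = 0.0512). Of 4 root cap genes BRN2 rose from 2.41 ± 0.555 to 5.15 ± 1.23 CPM and FEZ was at -0.95 on the log2 scale. The FEZ call ended without Col-0 ABA 1 (adjusted p = 0.0927), Col-0 ABA 2 (0.0553), Col-0 mock 1 (0.0834) or Col-0 mock 2 (0.0665). Of 19 cell cycle genes 6 rose, with PCNA1 at 0.37 and CYCB1;4 at 0.33. Of 13 photosynthesis genes 2 fell, PSAF at -0.70 and LHCB3 at -0.87, the latter lost without Col-0 ABA 3 (adjusted p = 0.0669), Col-0 mock 1 (0.0757) or Col-0 mock 2 (0.0583). Of 13 auxin genes 3 rose and 2 fell, with GH3.3 at -2.12 and GH3.5 at -0.58, and here the median (0.09) and the mean (-0.17) differed in sign. Of 9 cytokinin genes 6 fell and 1 rose, with ARR8 at -0.45 and ARR16 at 1.81. All 3 jasmonate genes that passed, of 5, rose, JAZ1 by 0.85 and JAZ7 by 2.41. The list jasmonate response passed without Col-0 ABA 3 (adjusted p = 0.0432) or Col-0 mock 1 (0.0249). With no filter on low counts it was at 0.028, and the list cell cycle and root meristem at 0.013. Of 4 defence genes FRK1 rose by 3.07 and PAD3 fell by 0.75 on the log2 scale. Of 11 clock genes 4 rose, with CCA1 at 3.28 and PRR5 at 0.43, and the PRR5 call ended without Col-0 ABA 2 (adjusted p = 0.0863).

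**Figure D2:**
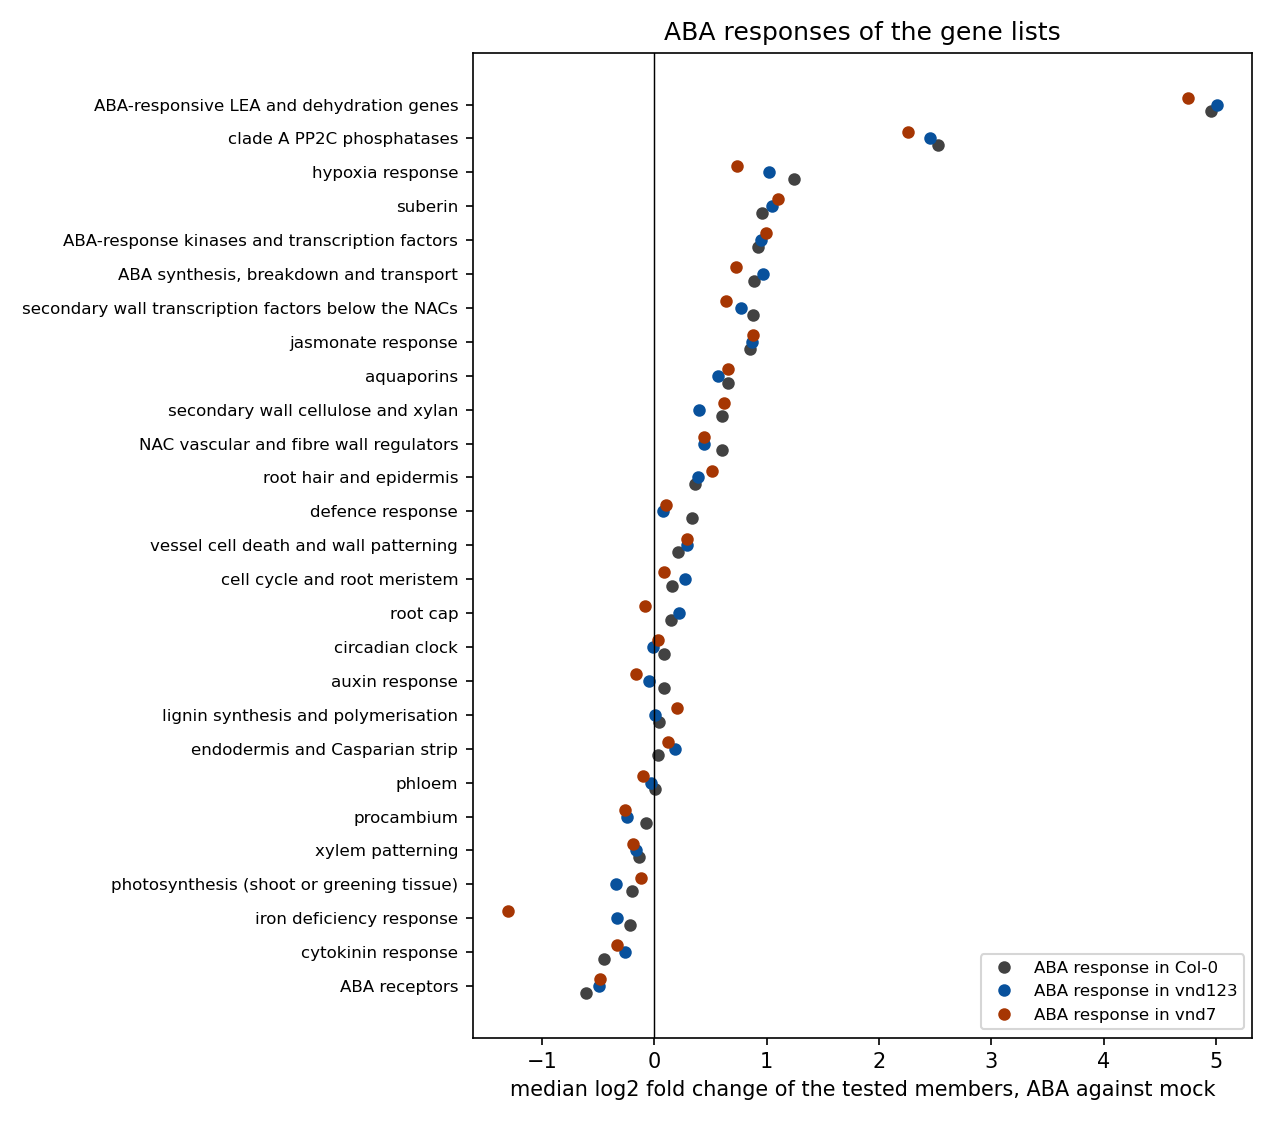
Median log2 fold change with ABA of the tested members of each of 27 gene lists, with a point for Col-0, vnd123 and vnd7 and a line at 0. Medians are as fitted, and those of the LEA list are 4.01, 4 and 3.87 with genes at the floor set to their bound. The iron list lies at -0.22 in Col-0, -0.33 in vnd123 and -1.30 in vnd7.

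The lists of ABA signalling, LEA and suberin genes that passed in Col-0 also passed in both mutants. In vnd123, 6757 genes passed, 3872 higher and 2885 lower, of which 1089 and 760 changed at least 2-fold. In vnd7, 6942 passed, 3916 higher and 3026 lower, of which 1195 and 737 changed at least 2-fold. With unscaled library sizes the higher and lower genes were 3085 and 3838 in vnd123 and 3053 and 4449 in vnd7. PYL6 changed by -5.07 ± 0.17 in vnd123 and -4.77 ± 0.16 in vnd7, ABI1 by 1.90 ± 0.09 and 2.06 ± 0.09, and CYP707A1 by 3.96 ± 0.15 and 3.85 ± 0.15. All 9 phosphatase genes and all 20 LEA genes rose in both (also adjusted over the list alone), with medians of 2.45 and 2.26 and of 5.01 and 4.75. In both, 7 of 11 receptor genes fell and 2 rose (7 and 2 in vnd123 and 7 and 3 in vnd7 adjusted over the list alone). Of 17 kinases and transcription factors, 12 rose and 1 fell in each (12 and 13 rose adjusted over the list alone). Of 14 ABA metabolism genes, 7 rose in vnd123 and 6 in vnd7, and 1 fell in each (7 rose and 1 fell in each adjusted over the list alone). Of 18 suberin genes, 17 rose in vnd123 and 16 in vnd7 (17 and 16 adjusted over the list alone), with ABCG6 at 1.71 ± 0.09 and 1.91 ± 0.10. These lists and the secondary wall transcription factors passed with an estimated correlation in both mutants, with adjusted p of at most 0.0353. LEA7 was at least 29800-fold higher in vnd7, and its ratio in vnd123 was 79900 (14300 to 3160000). MYB102, a large change in both mutants, was at least 423-fold higher in vnd123 and at least 420-fold in vnd7.

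Secondary wall genes also rose with ABA in the mutants. In vnd123, 14 of 19 cellulose and xylan genes rose (16 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.0921 with an estimated correlation). In vnd7, 17 rose (18 rose and 1 fell adjusted over the list alone), with a median of 0.62 (adjusted p = 0.0269 with an estimated correlation). GUX1 rose by 0.96 ± 0.10 in vnd123 and 1.48 ± 0.10 in vnd7, and IRX14-L by 1.89 ± 0.15 and 1.74 ± 0.14. Of 17 transcription factors below the NACs, 10 rose in vnd123 and 9 in vnd7 (11 and 11 adjusted over the list alone). MYB46 rose by 1.46 ± 0.15 and 1.21 ± 0.15 and MYB52 by 1.68 ± 0.14 and 1.91 ± 0.14. Of 10 NAC regulators, 2 rose in vnd123 (VNI2 by 0.55, VND4 by 0.38), and 4 rose and 1 fell in vnd7 (2, and 4 and 1, adjusted over the list alone), and the list passed in neither. In each mutant 8 of 16 genes of the list vessel cell death and wall patterning rose and 1 fell (8 and 9 rose adjusted over the list alone), with BFN1 at 2.49 ± 0.16 and 2.53 ± 0.16 (adjusted p = 0.263 and 0.202 with an estimated correlation). Its preset adjusted p of 0.041 in vnd123 became 0.0513 and 0.0509 without Col-0 ABA 2 and 3, 0.0529 without vnd123 ABA 1, and 0.0639 and 0.0561 without vnd123 mock 2 and 3, and that of 0.0259 in vnd7 became 0.0509 without vnd7 mock 2. Of 23 lignin genes, 6 rose and 6 fell in vnd123 and 11 rose and 4 fell in vnd7 (6 and 8, and 12 and 4, adjusted over the list alone). The list lignin synthesis and polymerisation passed in neither, with a median of 0.01 and a mean of -0.20 in vnd123. Its adjusted p of 0.055 in vnd7 became 0.0422 and 0.0487 without vnd123 ABA 2 and mock 2, 0.0432 and 0.0321 without vnd7 ABA 1 and mock 1, and 0.0194 with no filter on low counts. In the iron list, 7 genes fell and 1 rose in vnd123 (7 and 2 adjusted over the list alone), and 10 fell and 1 rose in vnd7 (10 and 1), with FIT at -1.53 ± 0.11 and -1.80 ± 0.11 (adjusted p = 0.435 and 0.182 with an estimated correlation). Aquaporins, hypoxia genes and root hair genes passed with the preset correlation in both mutants, with adjusted p = 0.28, 0.263 and 0.263 in vnd123 and 0.253, 0.405 and 0.182 in vnd7 with an estimated correlation.

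The test of the question in the title is whether the ABA change of a gene differed between genotypes. No gene passed this interaction in edgeR. For vnd123 against Col-0, 0 genes passed and 748 had an unadjusted p under 0.05, which is 3.58% of those tested. DESeq2 called 5 and had 858 at an unadjusted p under 0.05. For vnd7 against Col-0, 0 passed in edgeR and 0 in DESeq2, with 835 (4%) and 929 at an unadjusted p under 0.05. For vnd123 against vnd7, 0 passed in both tools, with 964 (4.62%) and 1041. The smallest adjusted p in edgeR were 0.786, 0.895 and 0.671. The 5 genes of DESeq2, named after their values were seen, had smaller values in vnd123: LAC17 at -0.71 (adjusted p = 0.00891), GLYI7 at -3.11 (0.00437), WCRKC1 at -2.69 (0.0168), AT1G44030 at -1.81 (0.0398) and AT2G40390 at -2.01 (0.0398). LAC17 was also the lignin gene with the smallest p in edgeR, at -0.71 ± 0.13 (adjusted p = 0.786). It went from 29 ± 0.325 to 72.7 ± 5.35 CPM in Col-0 and from 19.6 ± 2.48 to 30 ± 3.49 CPM in vnd123. A fit of only the groups compared called 1 gene for vnd123 against Col-0. Of other members with the smallest p of their list, CTL2 was at -0.34 ± 0.12 (adjusted p = 1) and MYB46 at 0.58 ± 0.21 (1) in vnd123 against Col-0. In vnd7 against Col-0, VND7 was at -1.69 ± 0.43 (adjusted p = 0.895) and FRO2 at -1.91 ± 0.49 (0.895). For vnd123 against vnd7, GUX2 was at -0.55 ± 0.11 (0.671) and MYB10 at 1.51 ± 0.33 (0.72). In the simulation, the interaction of vnd123 with Col-0 recovered 71.6% of 2-fold differences and 32.8% of 1.5-fold ones. Most differences of 1.5-fold would therefore have been missed at this depth and number of replicates. The simulated genes varied independently, and those changed were many and not among genes with few reads, so real recovery may be lower. In edgeR, GLYI7 at -3.08 (adjusted p = 0.786) and WCRKC1 at -2.66 (0.829) did not pass, so larger differences may be missed too.

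Most genes called in Col-0 were also called in the same direction in each mutant. Of these 6532 genes, 79.2% were so in vnd123 and 80% in vnd7. The sign of the log2 change, passed or not, was that of Col-0 for 98.8% and 98.9%. Called in both Col-0 and vnd123 were 3033 genes higher and 2142 lower, against 694 and 386 for independent lists, and 1 gene went in opposite directions. For Col-0 and vnd7, the counts were 3080 and 2148, against 702 and 404, and 1 went in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.877 for Col-0 and vnd123 and 0.883 for Col-0 and vnd7, with Spearman's rho of 0.801 and 0.786. These responses share no libraries. Over the 3916 genes higher in vnd7, the median change was 0.57 in Col-0 and 0.53 in vnd123 (adjusted p = 0.0555, and 0.435 with an estimated correlation). That adjusted p was 0.0397 with the replicate block and 0.00966 with unscaled library sizes. It was 0.0016 to 0.466 when 1 library was left out, and under the threshold in 9 of 18 cases, given below. Over the 3026 genes lower in vnd7 the medians were both -0.47 (adjusted p = 0.74). Over the 3872 genes higher in vnd123, the medians were 0.57 in Col-0 and 0.59 in vnd7, and over the 2885 lower ones -0.50 and -0.51 (adjusted p = 0.658 for both).

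Secondary wall genes were lower in mock-treated vnd123 roots than in Col-0. In vnd123 against Col-0, 127 genes passed, 26 higher and 101 lower. Of 19 cellulose and xylan genes, 11 were lower and 0 higher (14 adjusted over the list alone), with a median log2 change of -0.67 (adjusted p = 2.77e-05 with an estimated correlation). COBL4, needed for cellulose deposition, was at 18.8 ± 1.77 CPM in Col-0 and 8.16 ± 1.3 in vnd123 (SD, n = 3), a log2 change of -1.20 ± 0.10 (adjusted p = 1.44e-06). IRX9, GUX1 and the chitinase-like gene CTL2 changed by -0.92 ± 0.10, -0.93 ± 0.10 and -0.77 ± 0.09. Of 16 vessel death and patterning genes, 5 were lower (8 adjusted over the list alone), with XCP1 at -0.65, XCP2 at -0.69, TED7 at -0.80 and TED6 at -0.75 (adjusted p = 0.000306 with an estimated correlation). Of 10 NAC regulators, 3 were lower, the mutated VND1, VND2 and VND3 (4 adjusted over the list alone; adjusted p = 0.000306 with an estimated correlation), so this test in part restates the genotype. Of 17 transcription factors below them, SND2 (-1.45 ± 0.18), MYB46 (-1.13 ± 0.15) and MYB83 (-1.22 ± 0.23) were lower (6 adjusted over the list alone), and the list passed (adjusted p = 0.000358 with an estimated correlation). Of 23 lignin genes, 4 were lower (5 adjusted over the list alone), the laccase genes LAC4 (-0.86 ± 0.09), LAC11 (-0.59 ± 0.09) and LAC17 (-0.57 ± 0.10) and the peroxidase gene PRX66 (-0.66 ± 0.11), while the list was at adjusted p = 0.0979 with an estimated correlation. The MYB83 call ended without Col-0 mock 2 (adjusted p = 0.0735), vnd123 mock 1 (0.0554) or vnd123 mock 2 (0.0666).

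Photosynthesis genes, markers of shoot or greening tissue, were lower beside the wall genes in vnd123 mock. Of 13, RBCS1A (-1.47 ± 0.24) and LHCB1.3 (-0.79 ± 0.17) passed (5 adjusted over the list alone), with a list median of -0.45 (adjusted p = 0.0814 with an estimated correlation). The other vascular lists were not lower. The phloem median was 0.21 (adjusted p = 0.00268, and 0.0777 with an estimated correlation) and the procambium median 0.18 (adjusted p = 0.0223, and 0.413 with an estimated correlation), with 0 members called in either (0 adjusted over the list alone). The call of the procambium list ended without Col-0 mock 2 (adjusted p = 0.315), vnd123 mock 2 (0.128) or vnd123 mock 3 (0.0654). Suberin genes had a median of -0.14 (adjusted p = 0.0017, and 0.375 with an estimated correlation), with 0 of 18 called (3 lower adjusted over the list alone). That suberin call ended without Col-0 mock 3 (adjusted p = 0.235) or vnd123 mock 1 (0.0706). Auxin genes were higher as a list, with a median of 0.18 (adjusted p = 0.0332 with an estimated correlation), with 0 of 13 called (3 higher adjusted over the list alone) and GH3.5 at 0.44 ± 0.11 (adjusted p = 0.109, 0.0307 with DESeq2 and 0.0381 without Col-0 ABA 3). Of 18 aquaporin genes, PIP2;5 was higher by 1.56 ± 0.29 (1 adjusted over the list alone), a call lost without Col-0 mock 2 (adjusted p = 0.0836) or vnd123 mock 2 (0.087). The LHCB1.3 call ended without Col-0 mock 1, 2 or 3 (adjusted p = 0.149, 0.0973 and 0.0712), vnd123 mock 1, 2 or 3 (0.0601, 0.211 and 0.159) or vnd7 mock 2 (0.0532). In all, 10 of 27 lists passed, 9 to 11 when 1 library was left out, and 5 with an estimated correlation.

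The 5 largest increases in vnd123 mock were AT4G04223, from 1.2 ± 0.323 to 42.3 ± 2.02 CPM, the floral repressor gene MAF5 (2.69 ± 0.20), AT5G38005 (1.77 ± 0.12), GRP5 (1.48 ± 0.32) and the marneral synthase gene MRN1 (1.41 ± 0.24). The 5 largest decreases were the sucrose transporter gene SWEET12 (-5.34 ± 0.98), VND2, AT1G19530 (-1.98 ± 0.39), the acyltransferase gene SNG1 (-1.61 ± 0.31) and AT1G68200 (-1.59 ± 0.22). Leaving out single libraries ended 4 of these calls. For GRP5 the adjusted p was 0.0998, 0.191 and 0.104 without Col-0 mock 1, 2 and 3, and 0.195 and 0.186 without vnd123 mock 2 and 3. For SWEET12 it was 0.0516 without Col-0 mock 1 and 0.0512 and 0.0739 without vnd123 mock 1 and 2. For AT1G19530 it was 0.0652 and 0.0557 without Col-0 mock 2 and 3 and 0.107 and 0.142 without vnd123 mock 2 and 3. For SNG1 it was 0.0925 without Col-0 mock 1 and 0.0637 and 0.0886 without vnd123 mock 1 and 2. The count of 127 fell to 84 without vnd123 mock 2, and DESeq2 called 218.

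In ABA, the wall genes of vnd123 were again below Col-0. In vnd123 against Col-0, 227 genes passed, 30 higher and 197 lower. Of 19 cellulose and xylan genes, 13 were lower (14 adjusted over the list alone), with a median of -0.72 (adjusted p = 1.45e-05 with an estimated correlation). GUX1 was at 17.8 ± 1.25 CPM in Col-0 and 7.44 ± 0.379 in vnd123 (SD, n = 3), a log2 change of -1.26 ± 0.10. CTL2, COBL4 and IRX9 changed by -1.11 ± 0.09, -1.02 ± 0.10 and -0.90 ± 0.09. Of 16 vessel death and patterning genes, 6 were lower (9 adjusted over the list alone), with XCP1 at -0.95, TED7 at -0.90 and TED6 at -0.74 (adjusted p = 0.000159 with an estimated correlation). Of 23 lignin genes, LAC17 (-1.27 ± 0.09), PRX66 (-1.03 ± 0.11), LAC4 (-0.94 ± 0.09) and LAC11 (-0.81 ± 0.09) were lower (6 lower and 2 higher adjusted over the list alone; adjusted p = 0.017 with an estimated correlation). Of 10 NAC regulators, 5 were lower (6 adjusted over the list alone; adjusted p = 6.7e-05 with an estimated correlation), the mutated VND1, VND2 and VND3, XND1 (-3.97 ± 0.64) and VND4 (-0.47 ± 0.10), so here too the test in part restates the genotype. The VND4 call ended without Col-0 ABA 2 (adjusted p = 0.129) or vnd123 ABA 1, 2 or 3 (0.0685, 0.0601 and 0.0784), and that of VND1 as given above. Of 17 transcription factors below them, 3 were lower (9 adjusted over the list alone; adjusted p = 0.000493 with an estimated correlation), with SND2 at -1.39 ± 0.17 and LBD30 at -0.94 ± 0.18. Of 13 photosynthesis genes, 4 were lower beside them (12 adjusted over the list alone), with a median of -0.65 (adjusted p = 0.0477 with an estimated correlation), with LHCB4.1 at -0.68 ± 0.13 and RBCS1A at -1.28 ± 0.25. The LBD30 call ended without Col-0 ABA 1 (adjusted p = 0.0667), Col-0 ABA 2 (0.0727) or vnd123 ABA 3 (0.0787), the LHCB4.1 call without Col-0 ABA 2 (0.116), vnd123 ABA 2 (0.076) or vnd123 ABA 3 (0.0594), and the RBCS1A call without Col-0 ABA 2 (0.0965).

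The 5 largest decreases in vnd123 under ABA were BCAT-2, DIN2, SEN1, AT3G15450 and VND2. The aminotransferase gene BCAT-2 changed by -4.40 ± 0.56 (adjusted p = 0.000134), the dark-inducible glucosidase gene DIN2 by -3.78 ± 0.53 (adjusted p = 0.000335), the dark-inducible gene SEN1 (AT4G35770) by -3.58 ± 0.83 (adjusted p = 0.0407), AT3G15450 by -2.38 ± 0.53 (adjusted p = 0.0307) and VND2 as given above. AT3G15450 was at 309 ± 142 CPM in Col-0 and 58.8 ± 44.7 in vnd123 (SD, n = 3). The largest increases were AT4G04223 (5.75 ± 0.24), MAF5 (2.71 ± 0.20), AT5G38005 (2.05 ± 0.12), AT3G32047 (1.16 ± 0.24) and MAF4 (1.12 ± 0.13). Without Col-0 ABA 1 the adjusted p was 0.12 for SEN1, 0.0955 for AT3G15450 and 0.124 for AT3G32047, and without Col-0 ABA 2 it was 0.146 for SEN1 and 0.176 for AT3G15450. Without vnd123 ABA 2 it was 0.2 for SEN1 and 0.183 for AT3G15450, without vnd123 ABA 3 it was 0.135, 0.135 and 0.0538 for SEN1, AT3G15450 and AT3G32047, without vnd123 ABA 1 it was 0.075 for AT3G32047, and without vnd7 ABA 1 it was 0.0515 for SEN1. PIP2;5 was the aquaporin called, higher by 1.42 ± 0.26 (1 adjusted over the list alone). Of 20 LEA genes, XERO1 was lower, at -1.08 ± 0.26 (adjusted p = 0.0438; 2 adjusted over the list alone), and its call ended without Col-0 ABA 1 and 2 (0.195 and 0.3), Col-0 mock 1 (0.0516), vnd123 ABA 1, 2 and 3 (0.0649, 0.183 and 0.174), vnd123 mock 1, 2 and 3 (0.0504, 0.0572 and 0.0591), and vnd7 ABA 1, 2 and 3 (0.0612, 0.0547 and 0.0528). The lists hypoxia response and iron deficiency response passed with the preset correlation (adjusted p = 0.0299 and 0.0244) and not otherwise (adjusted p = 0.647 for both with an estimated correlation). The hypoxia call ended without Col-0 ABA 1 (adjusted p = 0.161), vnd123 ABA 1 (0.245) or vnd123 ABA 3 (0.119), and the iron call without Col-0 ABA 1 (0.161), Col-0 ABA 3 (0.652), vnd123 ABA 1 (0.146) or vnd123 ABA 3 (0.119). In all, 8 lists passed, 6 to 10 when 1 library was left out. The count of 227 fell to 135 without Col-0 ABA 1, 116 without Col-0 ABA 2 and 121 without vnd123 ABA 2, and DESeq2 called 398.

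**Figure D3:**
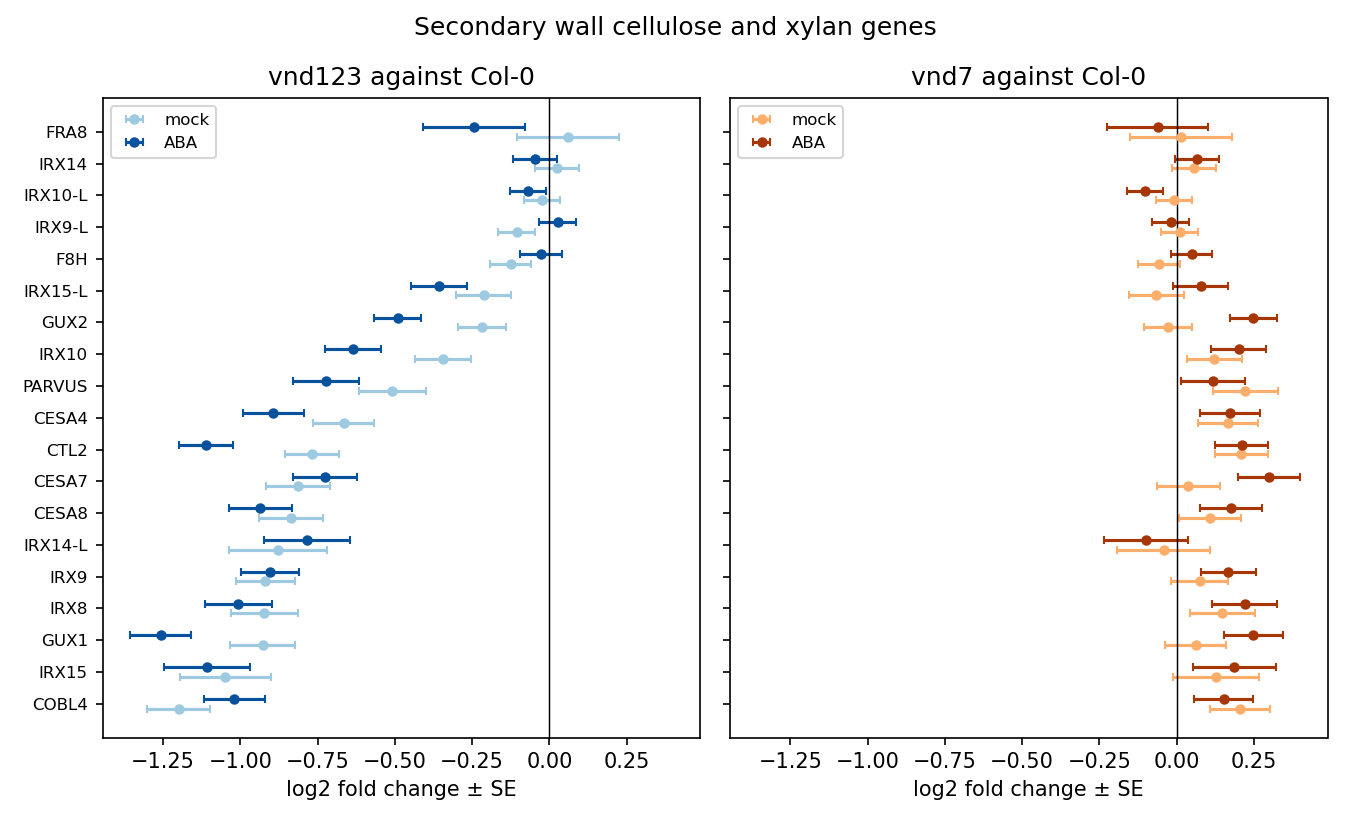
Log2 fold change ± SE of each of 19 cellulose and xylan genes in vnd123 (left) and vnd7 (right) against Col-0, with points for mock and ABA and a line at 0. Medians are -0.67 in mock and -0.72 in ABA for vnd123, and 0.06 and 0.17 for vnd7.

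Few genes passed between vnd7 and Col-0, and the cellulose and xylan genes were not lower in vnd7 as a list. In mock, 14 genes passed, 10 higher and 4 lower (DESeq2 called 31, 14 higher and 17 lower), and 1017 (4.87%) had an unadjusted p under 0.05. In ABA, 34 passed, 16 higher and 18 lower (DESeq2 called 147, 74 higher and 73 lower, and a fit of only these groups 56), and 2665 (12.8%) had an unadjusted p under 0.05, against 2143 (10.3%) for vnd123. The cellulose and xylan median was 0.06 in mock and 0.17 in ABA, with 0 of 19 called in either (0 adjusted over the list alone), at adjusted p = 0.476 and 0.932 with an estimated correlation. With the preset correlation the list secondary wall cellulose and xylan passed as higher in mock (adjusted p = 0.0375) and ABA (0.00306). The mock call ended without Col-0 ABA 2 (adjusted p = 0.0504), Col-0 mock 3 (0.493), vnd7 mock 1 (0.0847) or vnd7 mock 3 (0.22), and the ABA call without vnd7 ABA 2 (0.0668). The list lignin synthesis and polymerisation passed as lower in mock with the preset correlation (adjusted p = 0.0297), with a median of -0.07 and a mean of 0.01 (adjusted p = 0.476 with an estimated correlation). That call ended without Col-0 ABA 2 (adjusted p = 0.0508), Col-0 mock 1 (0.0594), Col-0 mock 3 (0.123) or vnd7 mock 2 (0.338). The largest increases in mock were AT1G75945, with a ratio of 995 (178 to 39300), AT4G04223 (4.66 ± 0.22), MAF5 (2.37 ± 0.20), AT5G38005 (1.23 ± 0.12) and MAF4 (1.12 ± 0.13). In ABA they were AT1G75945, at least 206-fold higher, AT4G04223 (5.22 ± 0.24), AT5G38005 (1.66 ± 0.12), MAF5 (2.07 ± 0.20) and AT3G56210 (1.06 ± 0.09). The decreases past the rule in mock were VND7, AT1G09890 (-0.98 ± 0.16) and LAC11 (-0.58 ± 0.09, adjusted p = 0.00977), the lignin gene called in both treatments (1 adjusted over the list alone). Without single libraries the adjusted p of AT1G09890 was 0.0755, 0.0842 and 0.108 (Col-0 mock 2, vnd7 mock 2 and vnd7 mock 3), and that of LAC11 was 0.0624, 0.0755, 0.15 and 0.108 (Col-0 mock 1, Col-0 mock 2, vnd7 mock 2 and vnd7 mock 3). In ABA LAC11 was at 145 ± 3.83 CPM in Col-0 and 89.9 ± 10.4 in vnd7 (adjusted p = 0.000796).

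In ABA, the largest decreases of vnd7 held genes of iron uptake. After VND7 came AT1G44030 (-2.19 ± 0.36), the iron transporter gene IRT1 (-2.19 ± 0.38), the ferric reductase gene FRO2 (-2.08 ± 0.37) and GRP3S (-1.78 ± 0.24). IRT1 was at 65.2 ± 26.5 CPM in Col-0 and 14.2 ± 5.16 in vnd7 (SD, n = 3; adjusted p = 0.0138). Of 16 iron genes, 2 were lower (11 adjusted over the list alone), with a median of -0.79 and adjusted p = 0.84 with an estimated correlation. The adjusted p of IRT1 was 0.0519, 0.0767, 0.0648 and 0.087 without Col-0 ABA 1, Col-0 ABA 3, vnd7 ABA 2 and vnd7 ABA 3, and that of FRO2 (0.0149 with all) was 0.0519, 0.0822, 0.0815 and 0.0976. AT1G44030 was at adjusted p = 0.0585 without Col-0 ABA 1 and 0.0675 without vnd7 ABA 1. Photosynthesis genes had a median of -0.39 in mock and in ABA, with 0 of 13 called (2 and 0 lower adjusted over the list alone), at adjusted p = 0.443 and 0.962 with an estimated correlation. With the preset correlation, the list photosynthesis (shoot or greening tissue) was at adjusted p = 7.68e-05 in ABA, and at 0.0972 without vnd7 ABA 3. In mock 8 lists passed with the preset correlation, 4 without vnd7 mock 3 and 12 without vnd7 mock 1, and 0 passed camera with an estimated one (2 at an unadjusted p under 0.05). In ABA 3 passed, 5 without Col-0 ABA 3 and 2 without vnd7 ABA 2, and 0 with an estimated one (1 at an unadjusted p under 0.05).

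Compared directly, in an added comparison that uses no Col-0 library as a control, vnd123 again had lower wall genes than vnd7. In mock 103 genes passed, 9 higher and 94 lower in vnd123, and in ABA 142, 26 higher and 116 lower. DESeq2 called 155 in mock, and 278 in ABA, 86 higher and 192 lower. Of 19 cellulose and xylan genes, 12 were lower in mock and 14 in ABA (13 and 14 adjusted over the list alone), with medians of -0.83 and -0.84 (adjusted p = 2.23e-06 and 1.46e-06 with an estimated correlation). Of 16 vessel genes 5 and 4 were lower (11 and 11 adjusted over the list alone), and of 17 wall transcription factors 3 and 2 (6 and 9 adjusted over the list alone). Photosynthesis genes had medians of -0.07 and -0.32 in this comparison, with 0 of 13 called (1 and 0 lower adjusted over the list alone; adjusted p = 0.868 and 0.466 with an estimated correlation). Over the mean of mock and ABA, also added, 418 genes passed for vnd123 against Col-0, 87 higher and 331 lower, and 42 for vnd7 against Col-0, 20 higher and 22 lower. The first count was 277 without vnd123 mock 2 and 658 with DESeq2. The second was 117 without vnd7 mock 1 and 184 with DESeq2. Unadjusted p under 0.05 were found for 2799 genes (13.4%) and 3053 genes (14.6%). Over that mean, 7 of 13 photosynthesis genes were lower in vnd123 (13 adjusted over the list alone), with a median of -0.55 (adjusted p = 0.0284 with an estimated correlation).

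A small set of genes differed from Col-0 in both mutants. In mock, 10 genes were called in the same direction, 9 higher and 1 lower, against 0.0125 and 0.0194 for independent lists. In ABA, 18 were, 9 higher and 9 lower, against 0.023 and 0.17, and 0 went in opposite directions in either. Simulated unchanged groups against the same controls called at most 2 genes per comparison in 20 draws and shared 0, so the simulated overlap could hardly be above 0. The covariance of the log2 changes was 0.0648 in mock and 0.0813 in ABA, and 0.0256 in the simulation, where the highest draw gave 0.0278. The simulation had 1 set of draws, not 1 per treatment, and its genes varied independently. Its range may therefore be too narrow to judge these values. The 3 Col-0 libraries of a treatment cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The genes called in both mutants and both treatments were 9, AT4G04223, MAF5, MAF4, AT5G38005, AT3G56210, the proton pump gene HA3, AT5G25560, AT5G35940 and LAC11, of which the last was lower and the others higher. HA3, AT5G25560 and AT5G35940 are named after their values were seen. The call of AT5G35940 in vnd123 ended without vnd123 mock 3 in mock (adjusted p = 0.0502), and in ABA without Col-0 ABA 1 or 2 (0.162 and 0.0635) or vnd123 ABA 1 or 3 (0.0923 and 0.109). In vnd7 it ended without Col-0 mock 1 or 3 (0.0624 and 0.1) or vnd7 mock 2 or 3 (0.0842 and 0.0716) in mock, and without Col-0 ABA 1 (0.0999) or vnd7 ABA 1 (0.1) in ABA. MAF5 was at 0.995 ± 0.256 CPM in Col-0 mock, 6.46 ± 0.424 in vnd123 mock and 5.18 ± 1.18 in vnd7 mock (SD, n = 3).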

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

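Chosen only after the result was seen were the permutation of list means, both tests of the wall genes, the tests of a shared Col-0 stock, of shared control values and of linkage, the direct comparison of the mutants and the mean over both treatments.

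Between the ABA responses of vnd123 and Col-0, 4 lists differed with the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05. Each was at adjusted p = 0.739 with an estimated correlation. The count of 4 was 0 to 9 with 1 library left out, as given below. The list NAC vascular and fibre wall regulators had an adjusted p of 0.0463 and a median difference of -0.23. Its adjusted p was 0.141 and 0.0925 without Col-0 ABA 1 and 3, 0.114 and 0.0778 without Col-0 mock 1 and 2, 0.117 and 0.148 without vnd123 ABA 1 and 3, 0.0967 and 0.192 without vnd123 mock 2 and 3, and 0.0517 and 0.0511 without vnd7 ABA 1 and 2. The list secondary wall cellulose and xylan had an adjusted p of 0.0463 and a median difference of -0.08. Leaving out single libraries gave 0.172 and 0.102 without Col-0 ABA 1 and 2, 0.419 without Col-0 mock 3, 0.117 and 0.0807 without vnd123 ABA 1 and 2, 0.203 and 0.0774 without vnd123 mock 2 and 3, and 0.0517 and 0.0511 without vnd7 ABA 1 and 2. The list lignin synthesis and polymerisation had an adjusted p of 0.0307 and a median difference of -0.06. With 1 library left out it was 0.141 without Col-0 ABA 1, 0.0892 without Col-0 mock 2, 0.106 and 0.148 without vnd123 ABA 1 and 3, and 0.0639 without vnd123 mock 2. The list endodermis and Casparian strip had an adjusted p of 0.0307 and a median difference of 0.16. Its adjusted p was 0.0599 without Col-0 ABA 1, 0.0778 without Col-0 mock 2, and 0.0967 without vnd123 mock 2.

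Between the responses of vnd7 and Col-0, 7 lists differed with the preset correlation and 0 with an estimated one, where 2 had an unadjusted p under 0.05. The count of 7 was 1 to 11 with 1 library left out, as given below. The list lignin synthesis and polymerisation had an adjusted p of 0.0203 and a median difference of 0.12, and adjusted p = 0.473 with an estimated correlation. Leaving out single libraries gave 0.11 without Col-0 ABA 3, 0.0835 without Col-0 mock 1, 0.191 without vnd7 ABA 2, and 0.3 and 0.0746 without vnd7 mock 2 and 3. The list procambium had an adjusted p of 0.00568 and a median difference of -0.39, and adjusted p = 0.473 with an estimated correlation. With 1 library left out it was 0.0721 without Col-0 ABA 3, 0.164 without vnd7 ABA 2, and 0.0961 without vnd7 mock 3. The list suberin had an adjusted p of 0.0248 and a median difference of 0.17, and adjusted p = 0.628 with an estimated correlation. Its adjusted p was 0.138 without Col-0 ABA 3, 0.0767 and 0.281 without Col-0 mock 1 and 3, 0.292 and 0.237 without vnd7 ABA 2 and 3, and 0.128 and 0.0746 without vnd7 mock 2 and 3, and 0.0529 with no filter on low counts. The list root hair and epidermis had an adjusted p of 0.0248 and a median difference of 0.12, and adjusted p = 0.473 with an estimated correlation. Leaving out single libraries gave 0.0775 and 0.0835 without Col-0 ABA 2 and 3, 0.0767 without Col-0 mock 1, 0.164 without vnd7 ABA 2, and 0.251 without vnd7 mock 3. The list auxin response had an adjusted p of 0.0124 and a median difference of -0.28, and adjusted p = 0.274 with an estimated correlation. With 1 library left out it was 0.0721 without Col-0 ABA 3, and 0.0961 without vnd7 mock 3. The list hypoxia response had an adjusted p of 0.000862 and a median difference of -0.50, and adjusted p = 0.473 with an estimated correlation. Its adjusted p was 0.0874 without vnd7 mock 3. The list iron deficiency response had an adjusted p of 8.12e-14 and a median difference of -0.91, and adjusted p = 0.272 with an estimated correlation.

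Between the responses of vnd123 and vnd7, 5 lists differed with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. The count of 5 was 3 without vnd123 mock 1. The list secondary wall cellulose and xylan had an adjusted p of 0.000792 and a median difference of -0.16, and adjusted p = 0.337 with an estimated correlation. The list lignin synthesis and polymerisation had an adjusted p of 2.13e-07 and a median difference of -0.15, and adjusted p = 0.307 with an estimated correlation. The list cell cycle and root meristem had an adjusted p of 0.0149 and a median difference of 0.12, and adjusted p = 0.307 with an estimated correlation. Leaving out single libraries gave 0.0753 without vnd123 ABA 1, 0.0572 without vnd123 mock 1, 0.0634 without vnd7 ABA 3, and 0.102 without vnd7 mock 2. The list photosynthesis (shoot or greening tissue) had an adjusted p of 0.0216 and a median difference of -0.27, and adjusted p = 0.726 with an estimated correlation. With 1 library left out it was 0.0602 without Col-0 ABA 1, 0.0506, 0.0613 and 0.0529 without Col-0 mock 1, 2 and 3, 0.385 without vnd123 ABA 3, 0.401 without vnd123 mock 1, 0.319 and 0.432 without vnd7 ABA 1 and 2, and 0.61 without vnd7 mock 3, and 0.0743 with no filter on low counts. The list iron deficiency response had an adjusted p of 1.14e-09 and a median difference of 0.58, and adjusted p = 0.307 with an estimated correlation.

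In the exact two-sided permutation of list means, with genotypes exchanged within each treatment, 400 groupings were run for each of 27 lists. For vnd123 against Col-0, 0 lists had a permutation p under 0.05 and the smallest adjusted permutation p was 0.867. For vnd7 against Col-0, 3 had, with a smallest adjusted permutation p of 0.27, and for vnd123 against vnd7, 3 had, with 0.0675. Between vnd123 and vnd7, the iron and jasmonate lists, with differences of 0.83 and -0.65, were at a permutation p of 0.005, the smallest that 400 groupings can give. The smallest for vnd7 against Col-0 was 0.01, for the wall transcription factors below the NACs, with a difference of -0.20. Exchanging genotypes separately in each treatment turns a difference between genotypes into an interaction, so this permutation is uninformative for lists that differ between genotypes alike in both treatments. The cellulose and xylan list, at 0.67 for vnd123 against Col-0 and 0.6 for vnd123 against vnd7, is such a list. The simulated interaction of vnd123 with Col-0 called 5 of 5 changed lists of 15 genes at 1.5-fold, and 0 of 22 unchanged ones, with the preset and with the estimated correlation, but its genes varied independently of each other.

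Secondary wall genes were lower in vnd123 than in Col-0 in both treatments, and beside them photosynthesis genes had a median of -0.45 in mock, with 2 of 13 lower (5 adjusted over the list alone; adjusted p = 0.0814 with an estimated correlation). A difference of the Col-0 libraries is argued against by the direct comparison with vnd7, where the cellulose and xylan genes had a median of -0.83 in mock. A lower share of all vascular tissue is argued against by the phloem and procambium lists, at 0.21 and 0.18, the lower of which decided the test. Fewer vessel cells and lower expression per cell both may be involved and were not tested, since bulk roots hold the cell types together. A difference of seed stock or growth between the lines goes with the genotype and cannot be separated from it in this design.

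Among the 28 calls shared by both mutants, 7.14% were also called between vnd123 and vnd7, in mock AT5G38005 (adjusted p = 0.0306) and ARP9 (adjusted p = 8.44e-05), so a difference of the Col-0 stock that both mutants share may account for the others, although choosing genes called in both favours small differences between them. The AT5G38005 call ended without vnd123 mock 1, 2 or 3 (adjusted p = 0.0735, 0.131 and 0.145) or vnd7 mock 2 or 3 (0.155 and 0.193), the call of ARP9 against Col-0 in vnd123 without Col-0 mock 1 (0.0632) or vnd123 mock 1 (0.052), and that of AT1G70500 in vnd123 ABA without Col-0 ABA 1 (0.125) or vnd123 ABA 2 (0.131). Chance values of the shared Col-0 libraries are argued against as the whole cause, because 17 of the 19 genes (89.5%, exact 95% binomial interval 66.9 to 98.7%), AT1G44030 and AT3G20270 excepted, had the same direction in both mutants in the other treatment, whose libraries are separate. Linkage to the mutated loci is argued against as the whole cause of calls in both lines. VND7 lies on another chromosome than VND1, VND2 and VND3, so no gene could be near loci of both lines, and 0 were. Within 200 genes of a locus of either line lay 3 of the 19 (15.8%, 3.38 to 39.6%). They were MAF4 and MAF5, 171 and 170 genes from VND3, and AT1G70500, 169 genes from VND7. The 16 others lay 247 or more genes away or on a chromosome without such a locus. Of all genes tested, 807 of 20866 lay that near a locus of vnd123 and 287 of 20868 that near VND7. An effect that both mutations have in common stays open too and was not tested.

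Iron deficiency genes had the largest median difference of these lists, in the ABA response of vnd7 against Col-0, where 8 of 16 members were lower adjusted over the list alone and 0 over all genes in edgeR or DESeq2 (adjusted p = 0.272 with an estimated correlation). Variation of the iron genes shared between libraries may give such a difference, with an exact two-sided permutation p of 0.11. A single library is argued against as the whole cause, because the median of the differences between group means, -0.80 with all 12 libraries, stayed between -0.58 without Col-0 ABA 3 and -1.18 without Col-0 ABA 2. That measure differs from the fitted median of -0.91. A difference that depends on VND7 stays open.

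Each comparison of 3 against 3 libraries has 10 groupings, so no share under 0.1 can be reached, and 1 of 10, the real one, gave as many genes in each. The real and the highest other counts were 6532 and 0 for the ABA response of Col-0, 6757 and 0 for vnd123 and 6942 and 1 for vnd7. In mock they were 127 and 1 for vnd123 against Col-0, 14 and 1 for vnd7 against Col-0 and 103 and 1 for vnd123 against vnd7, and in ABA 227, 34 and 142 against 0 each. Over both treatments, 1 of 30 groupings drawn, the real one, gave as many, with 418 against 9 for vnd123 and 42 against 25 for vnd7. This share is under 0.05 and is the smallest that 30 groupings can give. Both comparisons were added after the data were seen, so it does not exclude chance. For vnd7, whose count ran from 37 to 117 with 1 library left out, the margin was small. For the interactions the real count was 0, which each of the 30 groupings reaches by definition, so they decide nothing there. The highest others were 355 for vnd123 against Col-0, 1771 for vnd7 against Col-0 and 104 for vnd123 against vnd7. Those 3 groupings exchanged all ABA libraries of the genotypes and 1 mock library of each, which by construction carries the genotype differences, a structure of the samples, into the interaction. Whether these account for all of the 1771 genes, against 42 for vnd7 over both treatments, was not tested.

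Counts of lists with the preset correlation set the real grouping apart less. As many lists came from 3 of 10 groupings in the ABA response of Col-0 (13 lists, highest other 14), 2 in vnd123 (13 and 13) and 4 in vnd7 (13 and 17). In mock, 1 of 10 gave as many for vnd123 against Col-0 (10 and 8) and 1 for vnd7 (8 and 7), and in ABA 6 (8 and 14) and 8 (3 and 7). These shares cannot be under 0.1 either. For the interactions, as many came from 26 of 30 groupings for vnd123 against Col-0 (4 lists, highest other 14), 6 for vnd7 against Col-0 (7 and 9) and 24 for vnd123 against vnd7 (5 and 11). These counts decide nothing about chance, since the groupings carry genotype differences of lists into the interaction. With an estimated correlation the real and highest other counts were 8 and 0, 7 and 0, and 8 and 0 in the ABA responses of Col-0, vnd123 and vnd7. They were 5 and 0 for vnd123 and 0 and 0 for vnd7 against Col-0 in mock, and 6 and 3, and 0 and 1, in ABA.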

How the results depend on the processing

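Of the comparisons, the direct comparison of the mutants and the mean over both treatments were added after seeing the data, and they were run under the alternatives chosen before for the others. The counts for the ABA responses were within 1.5 times of 6532, 6757 and 6942 genes under all alternatives except the 2-fold minimum, and leaving out 1 library gave 5423 to 6803, 5503 to 6788 and 5991 to 7169. RLE factors, unscaled library sizes and the stricter filter moved no count of genes past 1.5 times, and RLE factors moved no count of lists so. The 2-fold minimum, which removes small changes by construction, left 1908, 1849 and 1932 genes in the responses of Col-0, vnd123 and vnd7. It left 53 of 127 in vnd123 and 8 of 14 in vnd7 in mock, 81 of 227 and 14 of 34 in ABA, 43 and 50 between the mutants, and 79 and 15 over both treatments.

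DESeq2 called more genes between genotypes, and the cause was not tested. It called 218 for vnd123 and 31 for vnd7 in mock, 398 and 147 in ABA, 155 and 278 between the mutants, and 658 and 184 over both treatments. Among these were 127 of the 127, 14 of the 14, 226 of the 227, 34 of the 34, 103 of the 103, 142 of the 142, 417 of the 418 and 42 of the 42 genes of edgeR. For the interaction of vnd123 with Col-0, DESeq2 called 5 genes and a fit of only the groups compared 1, against 0 in edgeR with all groups (748 at an unadjusted p under 0.05). Such a fit, which has fewer libraries for the spread, called 56 in vnd7 against Col-0 in ABA, 28 of them among the 34. With no filter on low counts, 64 genes passed for vnd7 over both treatments, against 42.

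With an estimated correlation, 8, 7 and 8 lists passed in the ABA responses of Col-0, vnd123 and vnd7 against 13 in each with the preset one. In the 3 interactions 0, 0 and 0 passed, with 1, 2 and 3 at an unadjusted p under 0.05. In mock 5 passed for vnd123 and 0 for vnd7 (2 at an unadjusted p under 0.05), and in ABA 6 for vnd123 and 0 for vnd7 (1 at an unadjusted p under 0.05). Over the genes higher in vnd7, the adjusted p for a smaller response of vnd123 than of Col-0, 0.0555, was 0.00966 with unscaled library sizes, and the cause was not tested. That scaling moved the median of all genes by less than 0.1 on the log2 scale.

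Leaving out 1 library gave 84 to 134 genes for vnd123 in mock, 84 without vnd123 mock 2. In ABA the range was 116 to 284, with 135 and 116 without Col-0 ABA 1 and 2, 121 without vnd123 ABA 2 and 284 without Col-0 ABA 3. Over both treatments it was 277 to 470 for vnd123, the lowest without vnd123 mock 2, and 37 to 117 for vnd7, the highest without vnd7 mock 1. The other genotype comparisons stayed within 1.5 times, at 10 to 19 and 24 to 46 for vnd7 in mock and ABA and 72 to 105 and 98 to 169 between the mutants, and edgeR called 0 genes in each interaction whichever library was left out. Lists passing with the preset correlation ranged from 0 to 9 in the interaction of vnd123 with Col-0, with 0 without Col-0 ABA 1 or vnd123 mock 2, 2 without Col-0 mock 2, vnd7 ABA 1 or vnd7 ABA 2, 7 without Col-0 ABA 3 and 9 without vnd123 ABA 2. For vnd7 with Col-0 they were 1 to 11, with 1 without vnd7 mock 3, 3 without Col-0 ABA 3 or vnd7 ABA 2, 4 without Col-0 mock 1 and 11 without Col-0 mock 3. For vnd123 with vnd7 they were 3 to 7, 3 without vnd123 mock 1. For vnd7 against Col-0 they were 4 to 12 in mock, 4 without vnd7 mock 3, and 2 to 5 in ABA, 5 without Col-0 ABA 3. The adjusted p for the response size was 0.0016 to 0.466, highest without vnd123 ABA 2. It was under 0.05 without Col-0 ABA 3, mock 1 or mock 3 (0.00195, 0.0116 and 0.0473), vnd123 ABA 3 or mock 1 (0.0016 and 0.0492) or vnd7 ABA 1, ABA 2, mock 1 or mock 3 (0.0254, 0.0144, 0.0261 and 0.0168).

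Pairing by replicate number was not settled. Deviations from the group means in 45 same-numbered pairs had a mean r of 0.02 (-0.096 to 0.202, 6 over 0.1), those of 90 other pairs a mean of -0.01, and 9 of 18 libraries correlated best with their own number of 3. The second mean largely follows from the first, as a group's deviations add up to 0. The photosynthesis mean, unlike the iron mean, was lowest in replicate 3 in each group. The block called more genes in each genotype comparison. Pairing may thus matter for some genes. With the replicate block, 6661, 6894 and 7097 genes passed in the ABA responses, 0 in each interaction, 135 and 17 in mock, 337 and 49 in ABA, and 105 and 179 between the mutants. Over both treatments it called 582 genes for vnd123 and 72 for vnd7, passed 7 lists in the interaction of vnd123 with Col-0, and put the response size at adjusted p = 0.0397.

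Of 445 values of genes named by the rule or in the text, 437 kept their direction and side of the threshold with DESeq2, 445 with RLE factors and 443 with the replicate block. The 8 others with DESeq2 and 2 with the block passed there and not in the fit reported. Leaving out each library kept 391, ended 51 calls and brought 3 past the threshold, and 0 were reversed. Depth limits genes with few reads, such as VND1 in vnd123.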

Other observations

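No test in this part was chosen after the result was seen. Some changes of the mutants' ABA responses have not been described above. In vnd123, the sugar transporter gene SWEET11 rose with a ratio of 766 (95% interval 212 to 6340), HAI2, a clade A PP2C phosphatase gene, with 1620 (289 to 63900), and GOLS2, a galactinol synthase gene, was at least 333-fold higher. HDK, PTR3 and TPS13 were among its largest decreases, at log2 changes of -5.12 ± 0.30, -4.81 ± 0.31 and -4.69 ± 0.54. In vnd7, the zinc finger gene SOM rose with a ratio of 2140 (384 to 84700), and the cytochrome P450 gene CYP82C4 fell from 57 ± 23.9 to 1.98 ± 1.21 CPM (SD, n = 3). Each is among the 10 largest changes of the mutant given, and none is said to differ from another genotype.

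Genes of the vascular stem cells and of hormone response changed in both directions in the mutants, with no list of them passing. Of 13 genes of the list procambium, 4 fell and 1 rose in each mutant (5 and 1 adjusted over the list alone). WOX14 was at -1.53 ± 0.20 and -1.62 ± 0.20 in vnd123 and vnd7, LBD4 at -1.61 ± 0.26 and -2.13 ± 0.27, and WOX4, which rose, at 1.72 ± 0.33 and 1.96 ± 0.32. That list was at adjusted p = 0.155 in vnd123 and 0.0578 in vnd7 with the preset correlation, and passed in vnd7 without vnd7 ABA 3 (0.0266) or vnd7 mock 1 (0.0321), or with no filter on low counts (0.0194). Of 9 genes of the list cytokinin response, 5 fell and 1 rose in each (5 and 1 adjusted over the list alone), with the response regulator genes ARR7 at -1.05 ± 0.28 and -1.69 ± 0.29 and ARR16 at 2.38 ± 0.30 and 2.24 ± 0.30 (adjusted p = 0.423 and 0.177 for the list). The ARR7 call in vnd123 ended without vnd123 mock 3 (adjusted p = 0.0591). Of 13 auxin genes, 3 fell and 3 rose in vnd123, and 5 fell and 1 rose in vnd7 (3 and 3, and 5 and 1, adjusted over the list alone). The conjugating enzyme genes GH3.3 and GH3.5 were at -1.92 ± 0.23 and -2.41 ± 0.23 and at -0.97 ± 0.12 and -0.92 ± 0.12 (adjusted p = 0.315 and 0.157 for the list). Of 19 genes of the list cell cycle and root meristem, 9 rose in vnd123 and 5 rose and 1 fell in vnd7 (10, and 5 and 1, adjusted over the list alone), with KN at 0.39 ± 0.07 in vnd123 and AUR2 at 0.33 ± 0.09 in vnd7. The AUR2 call ended without vnd7 ABA 2 (adjusted p = 0.0632), vnd7 mock 2 (0.0541) or vnd7 mock 3 (0.0627). The adjusted p of that list was 0.0626 in vnd123, 0.0353 without vnd123 mock 2 and 0.00398 with no filter on low counts, and 0.426 in vnd7. Of 11 genes of the list endodermis and Casparian strip, 3 rose in vnd123 and 2 rose and 1 fell in vnd7 (2, and 2 and 0, adjusted over the list alone), with CASP5 at 2.29 ± 0.14 and 2.13 ± 0.14 (adjusted p = 0.191 and 0.356 for the list).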
